A study of Mus musculus with 2 samples.

How the data were processed

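ATAC-seq peak lists of 2 libraries were used, the biological replicates of 1 group: hindbrain of B6NCrl mouse embryos at embryonic day 15.5, pooled over both sexes, with 78 embryos in replicate 1 and 62 in replicate 2, per the labels. The 2 replicates are 2 pools. The libraries were made by tagmentation with Nextera reagents, per the labels' protocols. The aligner, the peak caller, their versions, the shift of reads for the transposase and the read depth are not given in the sources used here. The lists are on mm10, per the labels, and the regions were checked against the chromosome lengths of the reference, GRCm38.p6 with the GENCODE M21 annotation.

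The 12 peak files comprised, for each replicate, a list thresholded on the irreproducible discovery rate (IDR), the ranked list behind it and a pseudoreplicated list. For both replicates together they comprised optimal and conservative IDR-thresholded sets, their ranked lists, a replicated list and a pooled pseudoreplicated list. Lists were called per replicate or on both, per the text listing beside the libraries. Each line of the authors' thresholded and pseudoreplicated lists is a summit, and several summits can share 1 interval. Unique intervals are called regions here, and the strongest summit gives a region's values. The signal value per summit is the authors' own deposited enrichment, and how it was scaled is not given in the sources used here. The −log10 p per summit is also the authors' deposited value, and it grows with the number of reads. The score column of the deposited lists is a display value of at most 1000, and in the authors' ranked lists the scores rise with the −log10 of the IDR. These values were used to describe, rank or filter regions within a list. The ranked lists also hold 16 columns of values per input, which were not used because they carry no sample names. The strength of matched regions was therefore compared between the replicates' own thresholded lists, and not within the ranked list of both replicates as had been planned. The alternative restricted to regions past the IDR threshold was not run for the same reason.

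The numbers of regions were 14186 and 20799 in the IDR-thresholded lists of replicates 1 and 2, 38782 and 60241 in their pseudoreplicated lists, 25514 in the optimal and 23102 in the conservative set. Since depth is unknown, precision is given only for shares of regions (Wilson 95% intervals). Regions on the 21 chromosomes were used. Random placement kept each region's length and chromosome, avoided assembly gaps of 1000 bp or more, and was run 20 times. A region counted as promoter when its midpoint lay within 1 kb of an annotated start site, and otherwise as exon, intron or intergenic. A gene's promoter counted as open when a region touched the 1 kb on either side of any of its annotated start sites, and an open promoter in both replicates was required for the list tests.

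The 24 gene lists (368 genes, of which 368 matched a symbol of the annotation), 32 motif consensus sequences, the tests and the alternatives were chosen from the tissue and age. Named genes followed a rule: for each list, the 2 members with the strongest promoter in the optimal set and up to 2 with no promoter region in either replicate, in the order of the list; the 10 genes with the most shared distal regions; the 10 genes with the strongest promoters; and a fixed set of hindbrain regulators and markers of other cells. Genes named outside it, such as Nfib, Slc1a3 and Aldh1l1 and the genes nearest to single regions, were chosen after their values were seen.

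Open promoters of each list were compared with those of all other protein-coding genes (21938 in all) by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Distal regions were regions of replicate 2 that overlapped a region of replicate 1 by at least 1 bp and had their midpoint over 1 kb from every protein-coding start site. Each was given to the nearest start site within 100 kb, and the sum over a list was set against 10000 random lists of the same size matched on the length of sequence nearest to each gene (two-sided permutation p, of which 0.0002 is the smallest possible). Motifs were searched on both strands in windows of 201 bp at the summit and 1000 bp to each side, and compared by an exact sign test over regions, with 10 shuffled forms of each consensus (7 for SP/KLF) as a control for base content. Lists with at least 5 genes open in both replicates were compared between the replicates by the median log2 ratio of signal values, as a percentile among 10000 random lists matched on strength.

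The tests were checked on simulated data. For promoters, 10 of 10 lists with a raised share and 8 of 10 with a lowered share were found, and 1 of 20 unchanged lists was called, over 21938 genes. For distal regions, 4 of 10 raised lists were found and 0 of 30 unchanged lists were called, so this test has low power. For motifs, 1 of 1 inserted motif was found and 1 of 31 others was called, over 3000 regions. The simulated summits and flanks had the same base composition, so this check does not cover calls that arise from base content. Alternatives covered the overlap, the promoter window, the distal reach and distance, the list of regions (optimal, conservative, pseudoreplicated), the stronger 50% of regions, equal numbers of regions, genes matched on promoter CpG content, the motif window and control, and each replicate left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and blastn 2.17.0 were used.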

Results

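Open chromatin was mapped by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into accessible DNA, in the hindbrain of mouse embryos at embryonic day 15.5. The hindbrain gives rise to the cerebellum, pons and medulla. The strain was B6NCrl, a C57BL/6 substrain. A single group of 2 biological replicates was compared, each a pool of hindbrains from embryos of both sexes, with 78 embryos in replicate 1 and 62 in replicate 2. No treatment, other tissue or other age was compared here, so the comparisons are between the replicates, between gene lists, and between parts of the genome. The replicate list that passed the authors' threshold on the irreproducible discovery rate (IDR) held 36873 summits in 14186 regions in replicate 1 and 56229 summits in 20799 regions in replicate 2. These regions had a median length of 946 bp in replicate 1 and 981 bp in replicate 2 and covered 13.6 Mb (0.50% of the genome) and 20.9 Mb (0.766%). The read depth is unknown here. Coordinates are on mouse build mm10. Genes and regions are not replicates: every p-value below compares genes or regions within these 2 pools, and intervals cover counting error only.

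The first comparison asked whether the 2 pools had the same accessible sites. The 10 strongest promoters of the authors' optimal set were open in both. That set was called on both replicates, so this was likely by choice and does not answer the question. The promoter region of Tmem218 on chromosome 9 (37207793 to 37208639), a ciliary membrane protein gene, had the highest signal value of any promoter region in the authors' optimal set, 24.8, with 25.9 in replicate 1 and 23.1 in replicate 2. It was followed by Hltf (23.3), which encodes a DNA translocase of replication fork repair, by Tars (23.3), the threonyl-tRNA synthetase gene, and by the mitotic phosphatase gene Cdc25c (22.5). The next 6 were 2610008E11Rik (22.5), Jpt2 (22.3), the isoleucyl-tRNA synthetase gene Iars (22.3), Depdc1a (22.2), Arrdc4 (21.5) and the cholesterol synthesis gene Hsd17b7 (21.4), and all 10 were open in both replicates. Of the regions of replicate 1, 96.4% (Wilson 95% interval 96.1 to 96.7) overlapped a region of replicate 2 by at least 1 bp, against a mean of 1.64% and a highest value of 2.02% for 20 random placements. Of the regions of replicate 2, 65.4% (64.8 to 66.1) overlapped a region of replicate 1, against a mean of 1.15% and a highest value of 1.34%. The regions without a partner numbered 508 in replicate 1 and 7190 in replicate 2, and they were weaker, with a median signal value of 5.88 against 8.60 for shared regions in replicate 1 and 5.10 against 8.50 in replicate 2.

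The strength of shared sites was ranked alike in the pools. The housekeeping promoter of Eef1a1, a translation elongation factor gene, had signal values of 14.4 and 14.4 in replicates 1 and 2, and that of Itpr1, the calcium release channel gene of Purkinje cells, 17.7 and 17.6. Promoters of weaker signal kept low values in both, as at the rhombomere gene Egr2 with 4.66 and 4.30 and the Purkinje cell gene Foxp2 with 4.68 and 5.36. Across 13555 matched regions Spearman's rho was 0.917 and Pearson's r 0.918, and the median log2 ratio of replicate 2 to replicate 1 was -0.04 (SD 0.22 over regions). The authors' −log10 p, which grows with the number of reads, had a median log2 ratio of 0.71 (SD 0.39 over regions) and was higher in replicate 2 at 95.9% of these regions. Both are the authors' own values from lists called separately, so a change in accessibility can be neither shown nor excluded from these ratios and ranks.

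The second comparison asked where open chromatin lay relative to genes. Regions gathered at start sites: 10978 of 21938 protein-coding genes (50.04%) had an open promoter in both replicates, meaning a region that touched the 1 kb on either side of an annotated start site. Another 86 genes were open in replicate 1 alone, 1442 in replicate 2 alone, and 9432 in neither. By midpoint, 76.9% of regions in replicate 1 and 62.1% in replicate 2 lay within 1 kb of a start site (69.5% ± 10.5, SD, n = 2), against 6.4% and 6.35% for randomly placed regions, which is 12.02 and 9.78 times as many. Introns held 9.69% and 17.1% of regions and intergenic sequence 11.8% and 18.5%, while random placement in replicate 1 gave 40.1% and 50.2%. Exons away from start sites held 1.58% and 2.25%, against 3.38% for random placement in replicate 1. Promoter regions were stronger and longer than the others, with a median signal value of 9.24 against 6.75 in replicate 1 and 8.24 against 5.61 in replicate 2, and a median length of 1007 against 694 bp and 1130 against 721 bp. The promoter share depended on the list, and was 37.0% in the authors' more permissive pseudoreplicated lists.

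The third comparison set 24 gene lists, fixed before the data were examined together with the tests and the alternatives, against all other protein-coding genes. In the developing hindbrain at this age, promoters of genes that most neurons and dividing cells use were mostly open in each replicate's IDR-thresholded list. Those of several neuronal subtypes, of oligodendrocytes, blood and vessel cells, of other organs and of Hox genes were mostly without a region there. Of the 24 lists, 18 differed from other genes, 3 with more open promoters and 15 with fewer, and each of the 18 had its direction in both replicates. The tests were Fisher's exact tests, two-sided, with Benjamini-Hochberg adjustment over the lists. A gene is described as closed or without a region when neither replicate's own IDR-thresholded list had one. Such a gene can still have a region in the more permissive pseudoreplicated lists. Of those named, Gfap (5.61), Pdgfra (4.95), Hoxa2 (4.02), Foxg1 (3.99), Nes (3.57) and Barhl2 (3.11) had a promoter region in the optimal set. With the pseudoreplicated lists 10 of the 15 lists with fewer open promoters lost their call. Each pool mixes the cell types of the hindbrain, so a promoter described as closed can still be open in some of them.

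Among housekeeping genes 14 of 15 were open (adjusted exact p = 0.00259, odds ratio 13.99), including Pgk1, a glycolytic kinase gene (14.96 and 13.8), and Eef1a1, and the exception was the polyubiquitin gene Ubc. Among general neuronal genes 14 of 16 were open (adjusted exact p = 0.00715, odds ratio 6.996). Nrxn1, a presynaptic adhesion molecule gene, had signal values of 14.3 and 14.8, and Syt1, the calcium sensor of synaptic vesicle release, 12.6 and 13.9. Dcx, a microtubule protein gene of migrating neurons, and Rbfox3, which encodes the neuronal nuclear antigen NeuN, had no promoter region at the IDR threshold. With the pseudoreplicated lists 16 of 16 general neuronal and 15 of 15 housekeeping genes were open in both replicates, Dcx, Rbfox3 and Ubc included. Among cell cycle genes 13 of 16 were open in both (adjusted exact p = 0.0283, odds ratio 4.33) and 16 of 16 in replicate 2. The mitotic checkpoint kinase gene Bub1 had values of 15.7 and 13.8 and the replication licensing gene Mcm3 15.5 and 17.1. Against random genes with a like promoter CpG content, none of the 3 lists passed. General neuronal genes also did not pass with the same number of regions in both replicates (56.3% open) or with only the stronger 50% of regions (25% open, a share under that of other genes).

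The rhombomere and isthmus, granule cell, Purkinje cell, progenitor, astrocyte and inhibitory lists did not pass. In the rhombomere and isthmus list 7 of 16 promoters were open (adjusted exact p = 0.656), with values of 14.3 and 16.6 at Pbx1, a Hox cofactor gene, and 10.3 and 9.48 at Pax5. Mafb (5.83 and 6.62) and Egr2, regulators of rhombomeres, were open in both. En1 and Gbx2, which position and maintain the midbrain-hindbrain boundary, had no region in either replicate, while En2 (4.71) and Pax2 (4.31) had one in replicate 2 alone. In the granule cell and rhombic lip list 11 of 20 were open (adjusted exact p = 0.824), led by Etv1 (10.3 and 10.9) and Meis1 (7.64 and 8.14). Zic1 was open with 6.87 and 5.99, and Atoh1 (5.05), the proneural gene of granule cell precursors, Pax6 (5.51) and Zic4 (4.35) had a region in replicate 2 alone. Barhl1 and Barhl2 had none. In the Purkinje cell list 11 of 16 were open (adjusted exact p = 0.252), among them Itpr1, Lhx1 (8.11 and 6.51), Lhx5 (5.85 and 4.02) and Foxp2, while Skor2 and Pcp2 had no region. In the list of progenitors and radial glia 10 of 16 were open (adjusted exact p = 0.519), with Nkx6-1 (9.44 and 10.1), Vim (8.03 and 8.91) and Sox2 (6.80 and 5.62) open and Nes and Notch1 without a region. In the astrocyte list 6 of 14 were open (adjusted exact p = 0.656), among them Nfia (7.34 and 7.81) and Sox9 (6.498 and 5.60), while Gfap and Aqp4 had none. Inhibitory lineage genes were open at 5 of 17 promoters (adjusted exact p = 0.121), with Slc6a1 (8.61 and 7.90), a GABA transporter gene, and Gata3 (7.16 and 7.002) open and Ptf1a and Tfap2b without a region. Against genes of like CpG content the rhombomere list (43.8% against 71.2%) and the inhibitory list (29.4% against 75.7%) passed as lower. In the optimal set the Purkinje cell, progenitor and astrocyte lists (92.9% open) passed as higher, as did the progenitor list with the pseudoreplicated lists (93.8% open), and with only the stronger 50% of regions the granule cell (5%), progenitor (6.25%), astrocyte and inhibitory lists passed as lower.

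Several neural lists had fewer open promoters than other genes. Excitatory lineage genes were open at 2 of 16 promoters (adjusted exact p = 0.00558), Pou4f1 (6.5 and 7.34) and Lhx2 (5.08 and 6.58), and the glutamate transporter genes Slc17a6 and Slc17a7 had none. Serotonergic and noradrenergic genes were open at 3 of 17 (adjusted exact p = 0.0120), among them Maoa (8.05 and 9.73), a monoamine oxidase gene. Tph2, the rate-limiting enzyme of brain serotonin synthesis, had a region in replicate 2 alone (5.34), and Fev, Lmx1b and Slc18a2 had none. Cranial motor neuron genes were open at 3 of 16 (adjusted exact p = 0.0189), with Nkx6-1 and Tbx3 (7.48 and 10.4) open and Phox2a and Phox2b without a region. Oligodendrocyte lineage genes were open at 1 of 14 (adjusted exact p = 0.00259): Olig2 had values of 6.25 and 4.64, Olig1 had a region in replicate 2 alone (5.64), and Sox10 and Pdgfra had none. Forebrain transcription factor genes were open at 2 of 19 (adjusted exact p = 0.00176), Arx (5.70 and 6.87) and Lhx2, and Foxg1 and Emx1 had no region in either replicate. The cranial motor list did not pass with replicate 2 alone or with the same number of regions in both replicates, nor the oligodendrocyte list with replicate 2 alone. All 5 lists failed to pass with the pseudoreplicated lists, and the excitatory list also in the optimal set.

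Markers of non-neural cells in or around the brain were mostly closed. Microglia and macrophage genes were open at 1 of 16 promoters (adjusted exact p = 0.00162), endothelial genes at 1 of 15 (adjusted exact p = 0.00176), and pericyte, meningeal and fibroblast genes at 0 of 16 (adjusted exact p = 0.000120). Slc2a1, the glucose transporter gene of the blood-brain barrier, was open in both replicates (8.10 and 6.25), the tight junction gene Cldn5 (4.57) and the VEGF receptor gene Kdr (5.37) in replicate 2 alone, and Pecam1, Cdh5, Csf1r and Spi1 in neither. Erythroid genes were open at 2 of 15 (adjusted exact p = 0.00715), Gypa (7.69 and 6.22) and Klf1 (5.89 and 5.99), and Gata1 and the adult globin genes Hbb-bs and Hbb-bt had no region. Choroid plexus and roof plate genes were open at 2 of 15 (adjusted exact p = 0.00715), with Foxj1, the regulator of motile cilia, open (7.50 and 6.88) and Ttr, Otx2 and Lmx1a closed. Of the lists of other tissues, liver genes were open at 3 of 15 (adjusted exact p = 0.0283), pluripotency and germline genes at 2 of 15 (adjusted exact p = 0.00715), and heart and skeletal muscle genes at 0 of 17 (adjusted exact p = 8.97e-05). The erythroid and microglial lists did not pass against genes of like CpG content, and the liver list (20% open against 17.0% for such genes) turned. The endothelial, choroid plexus and liver lists did not pass with the pseudoreplicated lists or the optimal set, the erythroid list with the pseudoreplicated lists, the liver list with a window of 2 kb, and the liver and pluripotency lists with the stronger 50% of regions.

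Hox genes, which give cells their position along the body axis, had almost no open promoters in the replicates' own IDR-thresholded lists. Of the 15 genes of paralogue groups 1 to 5, which pattern the hindbrain, 1 was open in both replicates (adjusted exact p = 0.00176), Hoxa1, with values of 5.70 and 6.97. Hoxa2, Hoxb1 and Hoxb2 had no region in either replicate. Of the 19 genes of groups 8 to 13, which pattern the trunk and tail, 0 were open in either replicate (adjusted exact p = 4.47e-05). With the pseudoreplicated lists 73.3% of the genes of groups 1 to 5 were open, which turned their direction against other genes and ended the call, and the genes of groups 8 to 13 stayed at 0. In the authors' optimal set, which is also IDR-thresholded, 6 of the 15 genes of groups 1 to 5 were open. That is 40% against 59.1% of other genes, and the list did not pass there. The genes of groups 8 to 13 were at 0 in that set too.

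**Figure D1:**
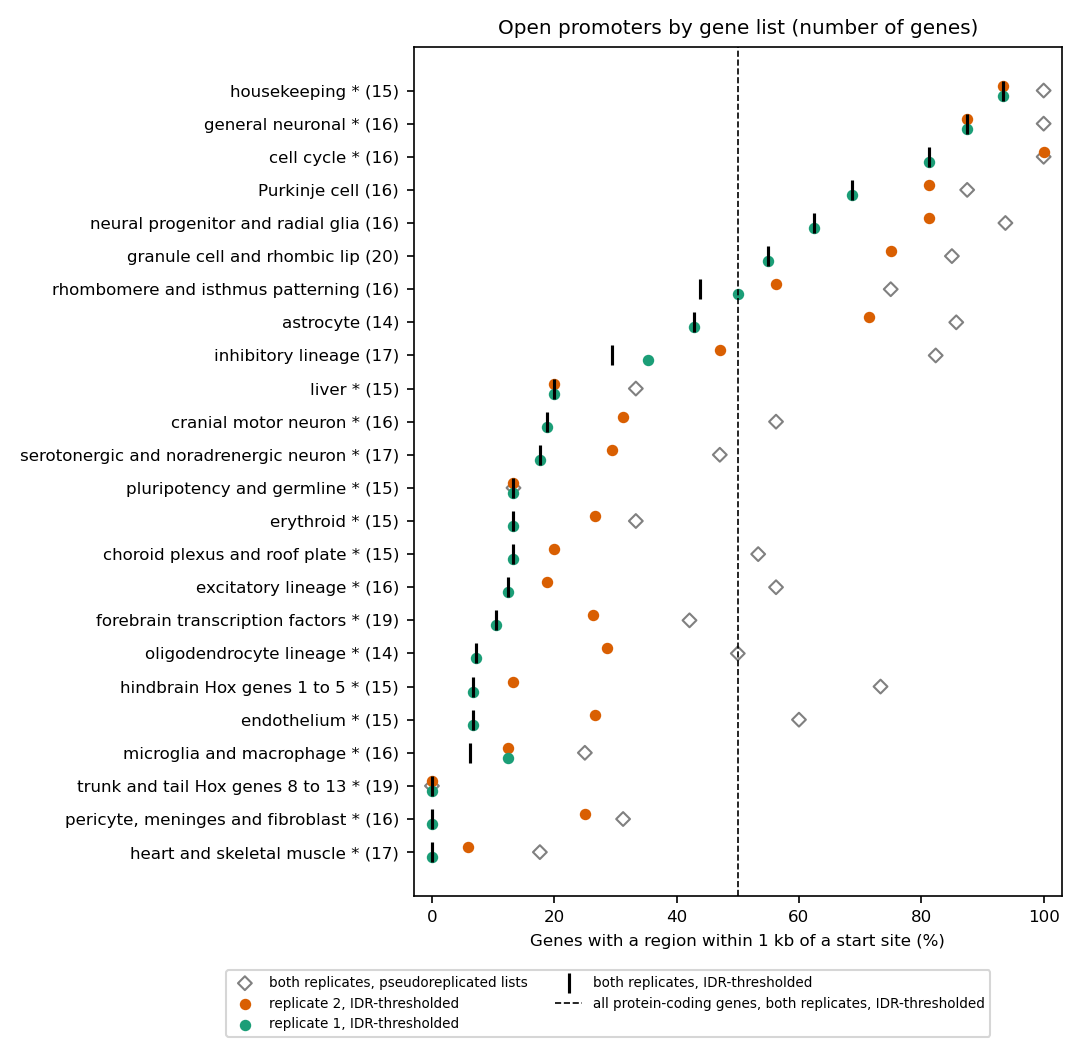
Share of genes with an open promoter (x axis, percent) in each of the 24 gene lists (y axis). Green points are replicate 1, orange points replicate 2 and black bars both replicates, all at the IDR threshold. Grey diamonds are both replicates with the pseudoreplicated lists. The dashed line marks all protein-coding genes, 50.04% open in both at the IDR threshold. It is not the baseline of the diamonds, for which 61.7% of all genes were open. Lists marked * had an adjusted p of 0.05 or less, 3 above the line (housekeeping, 14 of 15) and 15 below it (trunk and tail Hox genes, 0 of 19).

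The fourth comparison asked which gene lists had more open regions away from promoters. Astrocyte genes did: their 14 members had 19 distal regions shared by both replicates, in the neighbourhood of 10 genes, against 2.93 (95% of draws 0 to 8) for random genes with as much sequence nearest to them. That is 6.48 times as many (permutation p = 0.0002, the smallest that 10000 draws can give; adjusted permutation p = 0.0048), with 21 regions in replicate 1 and 39 in replicate 2. The strongest lay in an intron of Nfib, a transcription factor gene of gliogenesis (chromosome 4, 82512761 to 82513691, signal value 10.97, 7.45 kb from a start site). Others lay between genes near Slc1a3, the glial glutamate transporter gene (chromosome 15, 8629275 to 8629925, 9.30), in an intron of Aldh1l1 (chromosome 6, 90495181 to 90495957, 8.93), and near Sox9 (chromosome 11, 112810524 to 112812163, 7.70). Another lay in an intron of the water channel gene Aqp4 (chromosome 18, 15405113 to 15405522, 7.87), 1.56 kb from a start site of that gene. It was thus just outside the promoter window of 1 kb, in which Aqp4 had no region. Among the members, Gfap, Gja1 and Aldoc had no shared distal region. Slc1a3 and Sox9 are also in the list of progenitors and radial glia, which had 11 distal regions against 3.70 and did not pass (adjusted permutation p = 0.199). The astrocyte count describes the list and does not show that the regions are open in astrocytes. No other of the 24 lists passed, though the general neuronal and oligodendrocyte lists and the progenitors did with the conservative set and with the pseudoreplicated lists, and the granule cell and inhibitory lists with the latter. In all, 3453 distal regions were shared, 2829 of them within 100 kb of a start site of 2277 genes. The genes with the most were Cstad and Mef2c, a transcription factor gene of neurons and muscle, with 8 each, Tex14 with 7, Bahcc1 with 6, and Chd7, Gm11146, Maml3, Ncor2, Ralgapa2 and Rhbg with 5 each; regions of Mef2c, Bahcc1, Gm11146 and Rhbg lay within 10 kb of a microRNA gene.

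The fifth comparison asked which transcription factor motifs marked the summits of shared distal regions, relative to flanks centred 1000 bp to each side. The motif of CTCF, the architectural protein that bounds chromatin loops, was found within 100 bp of the summit in 5.04% of the 3453 regions and in 0.203% of flanks, 24.9 times as often (adjusted exact p = 3.47e-48), with ratios of 28.6 and 36.7 over all distal regions of replicates 1 and 2. The RFX motif, bound by regulators of ciliary genes, was found in 2.03% and 0.0434% (46.7 times, adjusted exact p = 5.09e-18), and its shorter core in 3.56% and 0.304% (11.7 times). The motif of CREB-type factors was found in 1.45% and 0.0579% (25.0 times). That of SP and KLF factors was found in 8.92% and 1.303% (6.84 times), and shuffled forms reached a ratio of 5.44. That of NFY was found in 15.4% and 6.62% (2.33 times). Over all distal regions of replicates 1 and 2 the ratios were lower for CREB-type factors (16 and 6.33), SP and KLF (6.47 and 4.95) and NFY (2.24 and 1.68). For RFX they were higher (82 and 75). The CREB-type and RFX ratios rest on few flank hits. Of 32 motifs tested by exact sign tests, 14 were more frequent at summits and 2 less frequent, all 16 with the same direction over the distal regions of each replicate. The 6-bp NFI motif was found in 40.02% and 22.5% (adjusted exact p = 3.66e-54) and the E-box CAGCTG in 21.2% and 9.60%, but shuffled forms of these motifs reached higher ratios, up to 2.52 and 3.57, than the 1.78 and 2.21 of the motifs themselves. Motifs of SOX factors (10.2% against 7.41%), POU factors (2.35% against 1.29%), ZIC (1.42% against 0.579%), ETS (1.36% against 0.159%), NRF1 (0.434% against 0%) and the proneural E-box (16.9% against 15.001%) were also more frequent. The homeodomain motif TAATTA (3.74% against 5.31%) and the GATA motif (1.04% against 2.27%) were less frequent at summits. Shuffled forms of TAATTA were depleted more than the motif itself, with a median ratio of 0.301 against 0.703. At summits 5 of its 10 forms were as frequent or more frequent. Shuffled forms of the GATA motif were depleted almost as much as the motif, with a median ratio of 0.548 against 0.459. At summits 9 of its 10 forms were as frequent or more frequent. At summits 1 shuffled form each of the proneural E-box (17.2%) and the ETS motif (4.29%) was more frequent than the motif itself, and the ZIC ratio, 2.45, was below the median of its shuffled forms, 6.58. Of the distal regions, 15.8% lay within 1 kb of a start site of a non-coding gene, and without these the POU and TAATTA motifs no longer passed, nor did they, SOX and the proneural E-box with the stronger 50% of regions, ZIC in replicate 1 alone, TAATTA in replicate 2 alone, or POU and NRF1 within 50 bp of the summit.

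**Figure D2:**
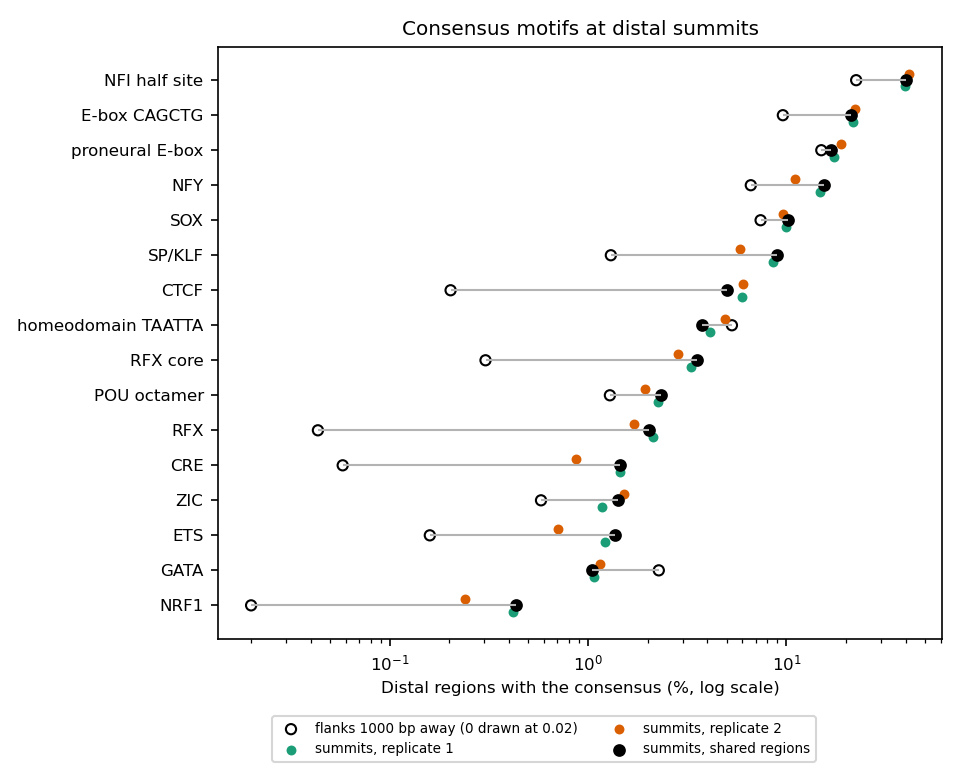
Percent of distal regions with a motif (x axis, log scale) for the 16 motifs that passed (y axis): at summits of shared regions (black points), in their flanks (open circles), and at summits of the distal regions of replicate 1 (green) and replicate 2 (orange); a flank value of 0 (NRF1) is drawn at 0.02. CTCF (5.04% against 0.203%) and RFX (2.03% against 0.0434%) are far from their flanks, while TAATTA and GATA lie below theirs.

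The sixth comparison divided the 4 Hox clusters at the paralogue groups. The part with groups 1 to 5 held 2 regions in replicate 1 and 5 in replicate 2 over 245 kb, or 0.0143 ± 0.00865 regions per kb (SD, n = 2), and the part with groups 8 to 13 held 0 in both replicates over 241 kb. Both replicates had a region at the start of Hoxa1 on chromosome 6 (52157934 to 52159256 in replicate 1, signal value 5.70; 52158034 to 52159032 in replicate 2, 6.97). A second shared region lay inside the span of Hoxa3 (52172250 to 52172987, 5.40; 52172231 to 52172995, 7.33). In the HoxD cluster on chromosome 2, replicate 2 alone had regions at the IDR threshold, at 74715723 to 74716350 and 74749328 to 74750452. The pseudoreplicated list of replicate 1 had regions at both places (74715812 to 74716270, 3.87, and 74749275 to 74750344, 4.46). The parts are the spans of the annotated genes and overlap in HoxC, and the difference between them, which was not tested, rests on few regions. With the pseudoreplicated lists the parts held 0.102 and 0.0124 regions per kb.

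**Figure D3:**
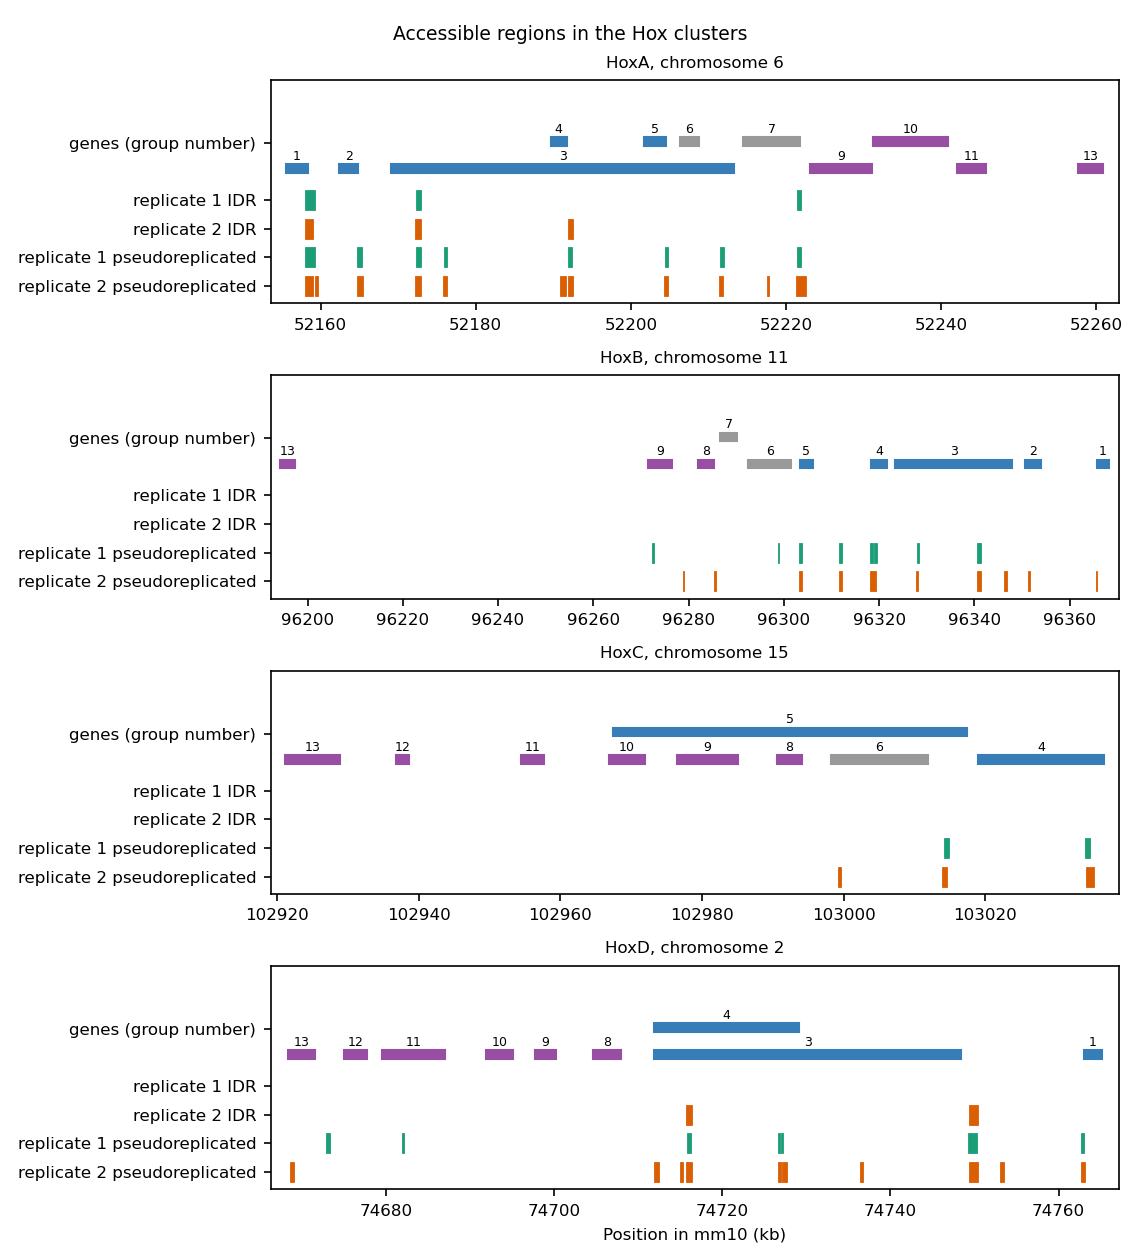
Maps of the 4 Hox clusters (x axis, position in kb on mm10) with genes of groups 1 to 5 in blue, 6 and 7 in grey and 8 to 13 in purple, and regions of replicate 1 in green and replicate 2 in orange, in lanes for the IDR-thresholded and the pseudoreplicated lists. IDR-thresholded regions lie over groups 1 to 5 (2 in replicate 1, 5 in replicate 2) and 1 over groups 6 and 7 in replicate 1, with 0 over groups 8 to 13.

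The last comparison asked whether promoters of any gene list differed in strength between the pools. Cell cycle genes had the highest place among random genes of like strength, with a median log2 ratio of replicate 2 to replicate 1 of 0.02 over 13 genes (percentile 87.7), followed by general neuronal genes with 0.01 over 14 genes (percentile 85.9) and the rhombomere list with 0.04 over 7 genes (percentile 83.8). The lowest were inhibitory lineage genes, with -0.12 over 5 genes (percentile 27.6), and astrocyte genes, with -0.08 over 6 genes (percentile 39.2). Purkinje cell (73.0), progenitor (65.9), granule cell (60.3) and housekeeping genes (75.5) lay between them in percentile. Of the 9 lists with at least 5 matched members, 0 lay outside the central 95% of random lists. The median over all 10978 genes was -0.04 (SD 0.20 over genes). The order changed with the pseudoreplicated lists, where forebrain (percentile 95.3) and excitatory genes (94.8) were highest and inhibitory genes lowest (2.84 over 14 genes). There cell cycle genes lay at 64.9, rhombomere genes at 16.8 and astrocyte genes at 86.6. Still no list lay outside the central 95%. No p-value was computed here, since the pools are 1 library each, and since the ratios compare separately called lists, a change in accessibility can be neither shown nor excluded.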

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

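The tests weighed here were chosen as tests of these explanations after the results they bear on were seen; the values with CpG-matched genes and with the pseudoreplicated lists come from alternatives chosen earlier.

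Some summits passed the authors' IDR threshold in the ranked lists, which no comparison used, and were missing from the thresholded lists: 169 in replicate 1, 237 in replicate 2, 285 for the optimal and 259 for the conservative set. Of these summits, 118, 165, 201 and 185 had the highest score of 1000. That score rises with the −log10 of the IDR. Signal values of the missing summits were not compared with those of kept ones. Of the missing summits, 43, 88, 112 and 97 lay on unplaced scaffolds. On the chromosomes they joined into 74 loci, 50 of them missing from all 4 lists, such as chromosome 17, 39843059 to 39846966, near Esp38, and chromosome 14, 19415649 to 19418963, near Gm21738.

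Nuclear copies of mitochondrial DNA do not account for these loci as a whole: 1.35% matched the mitochondrial genome, at chromosome 1, 24611586 to 24616165 (4580 bp at 99.96% identity), where this explanation needed most of them. A fixed set of loci left out by the authors may account for the gap, since 1.35% of the loci (the single one at chromosome 2, 181918518 to 181919274, near Polr3k) overlapped a kept region. That value lies between the bounds set for and against it, and with the rounded score, used first and then replaced by the IDR itself because some lines rounded up to the threshold, it was 13.7% of 95 loci. Repetitive sequence stays undecided too, with 47.3% of the loci soft-masked over most of their length against 0.2% of 500 kept regions, and no biological explanation was tested.

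Replicate 2 had 20799 regions and replicate 1 14186. The replicates are of 1 group, and the only biological explanation examined was a different mix of cells in the pools. Lower power to call regions in replicate 1 is a candidate explanation. Of the 7190 regions of replicate 2 alone, 88.2% were in the pseudoreplicated list of replicate 1. Of the 508 regions of replicate 1 alone, 96.9% were in that of replicate 2. Both shares are high, so this overlap cannot show which replicate had less power, nor tell low power from weaker accessibility. The −log10 p, which grows with the number of reads, was higher in replicate 2 at 95.9% of matched regions. A larger share of another cell type in the pool of replicate 2 stays undecided. The microglial, endothelial, pericyte, erythroid, liver, heart and muscle, and forebrain lists were pooled, without the choroid plexus and pluripotency lists. Their 39 promoters open in both replicates with the pseudoreplicated lists had a median log2 ratio of replicate 2 to replicate 1 of -0.02. That lay at percentile 49.6 of random genes of like strength. A value under the middle had been set as evidence against this explanation. The value lay there by less than the spread of the draws. At the IDR threshold replicate 2 had more open promoters than replicate 1 among markers of pericytes, meninges and fibroblasts (4 and 0). The same held for endothelium (4 and 1), erythroid cells (4 and 2), choroid plexus (3 and 2) and oligodendrocytes (4 and 1). It also held for forebrain genes (5 and 2) and heart and skeletal muscle genes (1 and 0). Counts were equal for microglia (2 and 2), liver (3 and 3) and pluripotency and germline (2 and 2). Over all genes replicate 2 had more (12420 and 11064). The globin genes Hbb-bs and Hbb-bt and the choroid plexus gene Ttr had no promoter region in either replicate, and the collagen gene Col1a1 had one in replicate 2 alone (5.496).

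The 15 lists with fewer open promoters than other genes included many with promoters poor in CpG, and the share of open promoters rose with CpG content over all genes, from 0.182% in the lowest decile to 90.2% in the highest. CpG content is not the whole cause, since 12 of the 15 stayed lower against genes of like CpG content; trunk and tail Hox genes were at 0 against 76.4%. The strictness of the IDR threshold alone is not the whole cause either, since 5 of the 15 stayed lower with the pseudoreplicated lists. The microglial list, among these 5, did not pass against genes of like CpG content. Genes were matched on CpG content only at the IDR threshold, so the joint effect of both was not tested. The other 10 lost their call with the pseudoreplicated lists to different degrees. Hox genes of groups 1 to 5 moved from 1 of 15 to 11 of 15 open and the odds ratio of endothelial genes from 0.0712 to 0.931, so strictness may account for these, while the odds ratios of liver genes (0.249 to 0.310) and erythroid genes (0.153 to 0.310) moved less, and both lists were 33.3% open against 61.7% of other genes, so it is not shown to account for these. No biological explanation was tested.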

How the results depend on the processing

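Alternatives that keep regions over 1 kb from every annotated start site, non-coding genes included, were chosen after seeing the data; all others were planned. Over lists and motifs, 303 values kept their direction and side of the threshold, 36 no longer passed, 16 newly passed and 17 reversed. Promoter regions of named genes were unchanged in 892 cases and gained or lost in 116. Left out of these counts are 18 distal lists and 15 motifs that passed in no setting, with 39 changes of direction among them. The heart and muscle, pericyte, and trunk Hox lists passed under every alternative run, as did the astrocyte list for distal regions (3.64 to 7.70 times the matched lists). No paired analysis was possible because there is 1 group. Overlap cannot be computed without a replicate, and the comparison of strength in regions past the IDR threshold of the joint ranked list was not run. Unknown depth limits every count of regions. The cause of the changes given here was not tested, except where fewer or more regions enter by construction.

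The share of replicate 1 regions found in replicate 2, and the reverse, was 92.7% and 63.2% when 50% of both regions had to overlap, 87.8% and 55.4% with the pseudoreplicated lists, 98.2% and 67.0% with the stronger 50% of regions, and 82.6% and 82.0% with as many regions in both. Spearman's rho was 0.940 with −log10 p in place of signal. The promoter share was 54.4% in the optimal set, 58.0% in the conservative set, 37.0% in the pseudoreplicated lists and 85.0% for the stronger 50% of regions, and ranged from 62.1% to 76.9% with a replicate left out.

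For promoters of gene lists, 6 lists passed as higher in the optimal set, with rhombomere (68.8% open), inhibitory (64.7%) and astrocyte genes (92.9%) reversed, of which astrocyte genes passed. The pseudoreplicated lists gave 9 lists that passed, 5 of them lower, with Hox groups 1 to 5 (73.3%), rhombomere (75%), inhibitory (82.4%) and astrocyte genes (85.7%) reversed. With the stronger 50% of regions granule cell (5%), Purkinje cell (25%), progenitor (6.25%) and general neuronal genes (25%) reversed, of which Purkinje cell and general neuronal genes did not pass, and with equal numbers granule cell genes (35%). Leaving out a replicate gave 42.9% to 71.4% for astrocyte genes, the upper value, without replicate 1, reversed. Against CpG-matched genes 0 lists passed as higher, and granule cell (55%), Purkinje cell (68.8%), progenitor (62.5%) and liver genes (20%) reversed. Distal regions gave 4 lists, all higher, with the conservative set and 6, all higher, with the pseudoreplicated lists. Motifs less frequent at summits numbered 1 with the stronger 50% of regions, 1 over 1 kb from every annotated start site, and 1 to 2 with a replicate left out (1 without replicate 1). Hox groups 1 to 5 held 0.102 regions per kb with the pseudoreplicated lists and 0.0326 in the conservative set, and 0.00815 to 0.0204 with a replicate left out; groups 8 to 13 held 0.0124 with the pseudoreplicated lists.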

Other observations

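The gene families, chromosome densities and strongest distal regions below, with their tests, and the count of genes near microRNAs were chosen after the results were seen; the test of regions near microRNAs was set before its result.

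Gene families differed widely in how many of their promoters were open: most ribosomal protein genes were, and almost no chemosensory receptor genes. The families were compared with all other genes, and not with genes of like promoter CpG content. Over all genes the share of open promoters rose from 0.182% in the lowest CpG decile to 90.2% in the highest. How much of the family differences follows CpG content was not tested. Of 83 cytosolic ribosomal protein genes 76 had an open promoter in both replicates, as had 69 of 75 mitochondrial ribosomal protein genes, 42 of 46 genes of NADH dehydrogenase subunits, 56 of 67 clustered histone genes and 321 of 394 zinc finger genes with a Zfp symbol. Of 1135 olfactory receptor genes 1 was open, of 327 vomeronasal receptor genes 1 (adjusted exact p = 7.24e-97) and of 42 beta-defensin genes 0. The clustered protocadherins, which give neurons their surface identity, were closed as well, with 4 of 57 open (adjusted exact p = 5.8e-12, 7.02% against 50.2% of other genes) and 5 with the pseudoreplicated lists. Sox genes were open at 8 of 19, and at 16 with the pseudoreplicated lists, while Nkx genes were open at 1 of 14 (adjusted exact p = 0.00124, 7.14% against 50.1%), and at 4 with the pseudoreplicated lists. Chromosome 11 had 7.99 regions per Mb in replicate 1 and 11.9 in replicate 2, the X chromosome 2.68 and 3.46, and the Y chromosome 0.0872 and 0.109.

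The 50 strongest regions away from start sites had signal values from 14.9 to 54.8. The strongest lay near Pak3 on the X chromosome (143482936 to 143483180, 54.8), and the region near Abcb11 on chromosome 2 (69355469 to 69355735, 51.9) held 129 bp that matched the mitochondrial genome at 100% identity. Of the 50, 5 had such a match, against 0 of the 11590 other regions away from start sites (exact p = 1.19e-12, two-sided). Soft-masked sequence made up most of 2 of the 50 and 111 of the others (4% against 0.958%, exact p = 0.0847).

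The genes with the most distal regions may owe part of their count to regions of neighbouring microRNA genes counted for the nearest protein-coding gene. Of the 59 regions of the 10 genes, 9 (15.3%) lay within 10 kb of a microRNA gene, against a mean of 2.30 (3.90%) for as many shared distal regions drawn at random (one-sided permutation p = 0.0006). Regions of a gene are neighbours, so that p is too small. By gene, 4 of the 10 had such a region and 6 of 89 other genes with 3 or more distal regions, but the 10 were chosen for having more regions, which gives each more chances, so these counts are no test. The 4 genes were Mef2c with Mir9-2, a microRNA gene of neural progenitors, Gm11146 with Mir99a and Mir125b-2, Rhbg with Mir3093 and Gm25641, and Bahcc1 with Gm47297. What drives accessibility at these sites was not tested.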
